A study of Mus musculus with 16 samples.

How the data were processed

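The samples were mitral cells, the output neurons of the olfactory bulb, of ICR mice at postnatal day 3 (P3) and postnatal day 6 (P6). Per the labels, cells had been electroporated in utero at embryonic day 12 with EYFP alone (control) or with EYFP and Kir2.1, an inward rectifier potassium channel that lowers neuronal excitability. Per the labels' protocols, fluorescent cells were picked by hand, the cDNA of each cell was amplified by 30 cycles of PCR, cells positive for EYFP and Pcdh21 (the gene Cdhr1, a marker of mitral and tufted cells) by PCR were kept, and the cDNA of 10 cells was pooled for each array. Each of the 4 groups held 4 arrays, hence 40 cells. The labels call the pools biological replicates without stating how many animals they came from, so p-values measure the spread between these pools, part of which may be technical.

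Per the file headers, each array was a 1-colour (Cy3) Agilent expression array read with Agilent Feature Extraction 10.7.3.1. The deposited scanner tables gave the processed spot signal as a background-subtracted intensity on a linear scale. Each array had 62976 spots, 59305 of them gene spots. The deposited value table of the series held the same signal divided by the array's 75th percentile over gene spots, as a comparison with the scanner values showed (ratio of the 2 sources 0.995 to 1.005 on all 16 arrays). That table is linear and not centred on genes, its medians per array lay between 0.0337 and 0.12, and no part of its scale or direction stayed unknown. All P3 arrays lay on slide 1 with scan 1 and all P6 arrays on slide 2 with scan 2, so age and slide cannot be told apart. The comparisons of Kir2.1 with control lay within a slide, where control pools occupied row 1 and Kir2.1 pools row 2, so the row of the slide and the treatment cannot be told apart either. No gene spot was saturated. The highest correlation between 2 arrays was 0.881, and no pair of arrays shared more than 0.002% of its values exactly, so no pool was counted as a duplicate.

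Control spots and spots marked as outliers were left out, and the spots of a probe were averaged. Of 55681 probes, 83 were left out because all their spots were outliers on an array. Gene symbols came from a table of RefSeq accessions for the assembly GRCm38.p6. Of 28116 probes with a RefSeq accession, 26582 received a symbol this way, and 29099 probes stayed unnamed. Between 34.3% and 41.1% of the probes were well above background on an array. Since that is under 50% of the probes, log2 signals were scaled by each array's 75th percentile over the 12103 probes that were well above background on all 16 arrays. A probe was tested where it was well above background on at least 4 of the 16 arrays, and the probe with the highest mean stood for its gene. This left 21070 features, 12035 named genes and 9035 unnamed probes. The number of arrays limits the precision of every value.

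All 16 arrays were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 12 residual degrees of freedom, 1.64 prior degrees of freedom and a prior SD of 0.64 on the log2 scale. The contrasts were Kir2.1 against control at P3 and at P6, the mean of both, P6 against P3 in control cells and in Kir2.1 cells, and the interaction of age and Kir2.1. Every adjusted p is from limma after Benjamini-Hochberg adjustment over the 21070 features of a contrast, with a threshold of 0.05. The 31 gene lists were tested with camera of limma with a preset correlation of 0.01 between genes, two-sided and adjusted over the 31 lists of a contrast. Every list was tested again with the correlation estimated from the data. A count adjusted over the list alone corrects for the list's own members only. Cell type scores, the means of a list's tested members on an array, were compared with exact two-sided permutation tests.

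Where no probe of a gene was well above background on any array of a group, the difference is given as at least N-fold. A gene with another probe well above background there has no such bound, even where its tested probe lay at background. The bound sets the mean of the brighter group against, for each array of the dim group, the higher of the lowest signal among probes well above background and the tested probe's own signal. Groups were called non-overlapping where every array of one lay above every array of the other. For the mean over P3 and P6 this was required at each age in the same direction, and it was not required for the interaction. With 4 arrays against 4, chance separates the groups in 2.86% of genes.

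The design, the tests, the gene lists and most alternatives were fixed before the data were examined. The genes named were, per contrast, up to 10 higher and up to 10 lower with the largest change among non-overlapping genes past the threshold, filled up to 5 by the lowest p where fewer passed. Members of the gene lists past the threshold, or up to 4 with the lowest p, were named too, as were Kcnj2, Cdhr1, Bmpr2, Fos, Arc, Egr1, Npas4 and Nr4a1. Names that are only a clone or predicted-gene identifier were left out. Alternatives chosen beforehand were quantile normalization, the deposited value table, no filter on dim probes, a filter at 8 arrays, the mean of a gene's probes, every probe tested separately, the replicate number as a block, array weights, a trended and robust prior, only the groups of a comparison, an estimated correlation, and leaving out each pool in turn. Added after seeing the data were scaling over all probes, the normexp background correction (offset 50) on median signals, and a fit with P6 control pools 2 and 4 only, because pools 1 and 3 held more signal from microglia or oligodendrocyte markers. A normexp version on mean signals, also chosen beforehand, was not run, since the scanner tables used here hold no mean signal column. A value that changed sign under an alternative was called reversed only where it passed the threshold in either setting.

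The fit and the list test were tested on simulated data, with the arrays' own residuals and 200 genes changed in the P6 Kir2.1 pools. For the comparison of Kir2.1 with control at P6 over 21070 features, 1.5% of genes changed by 1 on the log2 scale were recovered, 17.9% of those changed by 2 and 48.5% of those changed by 4. In that simulated comparison 2 unchanged genes passed the threshold, and the 1 shifted list was found with 0 other lists. The residuals of each gene were shuffled over the arrays separately, so correlation between genes was lost. The simulation therefore cannot show how often correlated lists, such as ribosomal protein genes (estimated correlation 0.372), pass by chance. Shuffling also gave the 4 groups the same spread. In the data the spread was larger at P6 (root mean square SD over features 1.51 in control, 1.52 in Kir2.1) than at P3 (1.18 and 1.33). Recovery and false calls under that unequal spread were not simulated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Unnamed probes are given only as counts. The results of some genes and of 1 gene list are not reported here.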

Results

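Gene expression was measured in mitral cells of the mouse olfactory bulb that carried EYFP alone or EYFP with Kir2.1, at P3 and P6. Each of the 4 groups held 4 arrays, and each array held the pooled cDNA of 10 hand-picked cells. Signal was well above background for 34.3% to 41.1% of the probes of an array. Across genes, the median correlation between pools of a group was 0.874 in P3 control, 0.847 in P3 Kir2.1, 0.803 in P6 control and 0.818 in P6 Kir2.1. Values are log2 signals relative to the 75th percentile of their array, as mean ± SD over 4 pools, and changes are differences of those means with their SE from limma.

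Kcnj2, the endogenous gene of Kir2.1, had a probe that was not well above background on any of the 16 arrays. It was not tested, and whether the probe reads the introduced cDNA is not known, so it checks nothing about the labels. Cdhr1, the marker by which cells had been kept, was bright in every group, at 3.31 ± 0.33 in P3 control, 2.75 ± 0.43 in P3 Kir2.1, 3.08 ± 0.33 in P6 control and 3.75 ± 0.25 in P6 Kir2.1. It did not pass the threshold with Kir2.1 at P3 (change -0.56, adjusted p = 0.795) or at P6 (0.66, adjusted p = 0.235), nor with age in control (-0.23, adjusted p = 0.721) or Kir2.1 cells (1.00, adjusted p = 0.112).

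The comparison of Kir2.1 with control at P3 asked which genes differ in young mitral cells that carry Kir2.1. Scg2, which encodes secretogranin II, a granin of dense-core vesicles, fell by 5.61 (SE 0.64, adjusted p = 0.0127), from -2.39 ± 0.57 to -8.0 ± 1.22. All 4 Kir2.1 pools lay below all 4 control pools, and 2 of the 4 were well above background. It was the only 1 of 12035 named genes past the threshold, with 730 genes at an unadjusted p under 0.05 against 602 by chance. The nearest others were Pik3cb, a catalytic subunit of phosphoinositide 3-kinase (-4.02, at least 3.78-fold, adjusted p = 0.0586), Inhbe, an inhibin subunit (1.38, adjusted p = 0.0694), and Fam53a (-4.70, adjusted p = 0.135). Arhgap22 (-4.34, at least 5.4-fold, adjusted p = 0.147), Farp1 (-1.22, adjusted p = 0.154), Osbpl9 (3.91, adjusted p = 0.154) and Rab39b (3.18, adjusted p = 0.154) followed. Pcdh7 (3.49) and Pipox (3.17, at least 2.53-fold) did not pass either. Groups did not overlap in 5.9% of named genes, where chance gives 2.86%.

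Of the 31 gene lists, 4 passed the list test at P3 and 0 of these with an estimated correlation. Ribosomal protein genes rose by a mean of 0.16, with 70 of 82 members positive (adjusted p = 8.07e-06; adjusted p = 0.736 with an estimated correlation), among them Rpl5 (0.70) and Rps15 (0.57). Late activity response genes, which follow neuronal activity within hours, fell by a mean of 0.56 (adjusted p = 0.0495; adjusted p = 0.356 with an estimated correlation), with 11 of 20 members negative. Their 1 called member was Scg2, and 3 members were lower when adjusted over the list alone. Genes of maturing neurons fell by 0.41, with 25 of 36 negative (adjusted p = 0.0409; adjusted p = 0.403 with an estimated correlation), among them Atp1b1, a subunit of the sodium-potassium pump (-1.0), and Aldoa, a glycolytic enzyme (-0.70). Heat shock and dissociation stress genes fell by 0.35, with 12 of 14 negative (adjusted p = 0.0409; adjusted p = 0.356 with an estimated correlation), among them Nfkbia (-1.01) and Hsph1 (-0.80). With limma, 0 members of the ribosomal, maturing and heat shock lists passed, also adjusted over the list alone, and 6, 8 and 1 had an unadjusted p under 0.05. The immediate early gene Npas4 (2.46, adjusted p = 0.871) and the BMP receptor Bmpr2 (1.11, adjusted p = 0.95) did not pass.

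The call of Scg2 at P3 ended without P3 control pool 1 (adjusted p = 0.0707) or 2 (0.0763) and without P3 Kir2.1 pool 3 (0.0854) or 4 (0.0587), and under 1 of 13 other settings (0.108). Leaving out 1 pool at a time ended the call of the late activity list for 10 pools, of the maturing list for 8 and of the heat shock list for 7, with adjusted p up to 0.211, 0.21 and 0.242, where the highest came without P3 control pool 3, P3 control pool 2 and P3 Kir2.1 pool 3. Of 13 other settings, 10, 7 and 9 ended these 3 calls, with adjusted p up to 0.356, 0.403 and 0.548.

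At P6 the same comparison gave 217 named genes, 114 higher and 103 lower with Kir2.1. Iqcb1, which encodes the ciliary protein nephrocystin-5, rose by 7.02 (SE 0.95, adjusted p = 0.00419), from -9.35 ± 1.00 to -2.34 ± 1.52, at least 38-fold. Snhg12, a host gene of small nucleolar RNAs, rose by 6.78 (SE 1.04, adjusted p = 0.00733), and Ptgis, prostacyclin synthase, by 5.51 (SE 0.97, adjusted p = 0.0159), at least 24.1-fold. Fastkd5, a mitochondrial RNA-binding protein, rose by 5.48 (SE 0.93, adjusted p = 0.0125), at least 18.5-fold. Kitl, the ligand of the Kit receptor, fell by 6.19 (SE 0.95, adjusted p = 0.00733), from -3.27 ± 1.80 to -9.46 ± 0.92, at least 25.1-fold. In all of these genes every Kir2.1 pool lay on the same side of every control pool. Other settings ended the calls of Ptgis (3 of 12, adjusted p up to 0.153) and Fastkd5 (3 of 13, 0.125). The calls of Snhg12 (1 of 13, 0.145) and Kitl (1 of 12, 0.0868) also ended under another setting.

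Other genes that fell at P6 were Slc24a2, a potassium-dependent sodium-calcium exchanger (-6.42, adjusted p = 0.0103), and Pcdhb16, a clustered protocadherin (-6.36, adjusted p = 0.0124, at least 22.6-fold), whose probe may also read close paralogs. Masp2, a protease of the lectin pathway of complement, fell by 5.95 (adjusted p = 0.0103). Asph fell by 5.78 (adjusted p = 0.0106), while its other 2 probes moved the other way. Nudt1 rose by 6.70, a call that ended without P6 Kir2.1 pool 4 (adjusted p = 0.0501). Penk, which encodes proenkephalin, was lower by -6.32 (SE 1.26, adjusted p = 0.0269), at least 28.4-fold. Its call ended without P6 control pool 1 (0.0509), 2 (0.0523) or 4 (0.0502) and without P6 Kir2.1 pool 2 (0.0573), 3 (0.0509) or 4 (0.0612). Other settings ended the calls of Slc24a2 (1 of 13, adjusted p up to 0.11), Masp2 (1 of 13, 0.132) and Asph (2 of 13, 0.884). They also ended those of Nudt1 (3 of 13, 0.0731) and Penk (1 of 12, 0.187).

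**Figure D1:**
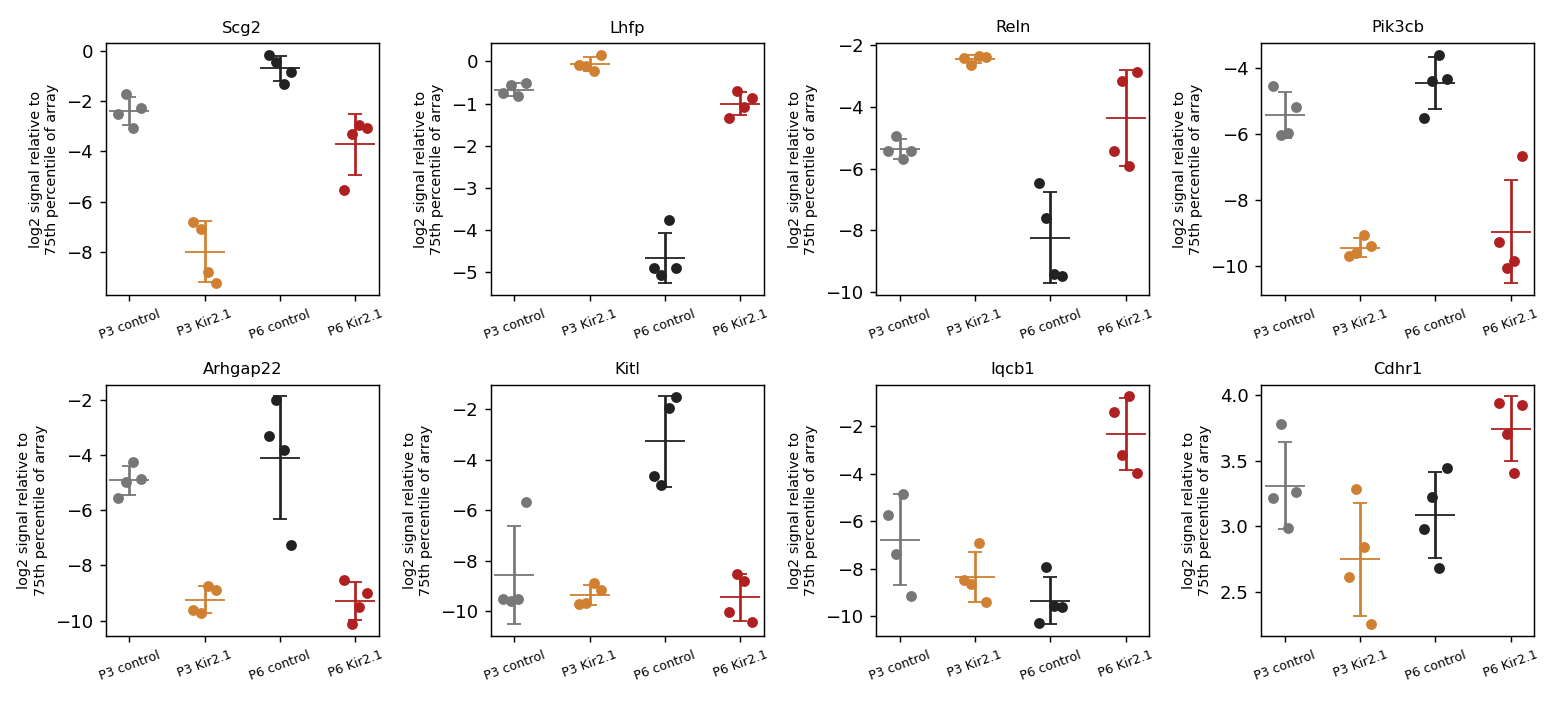
Log2 signal of 8 genes relative to the 75th percentile of each array (y axis) in the 4 groups (x axis). Points are pools, lines are means and bars are the SD over 4 pools; Scg2 falls from -0.68 to -3.71 between P6 control and P6 Kir2.1, and Lhfp lies at -4.67 in P6 control and -1.0 in P6 Kir2.1.

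Among list members at P6, Kcnip2, an auxiliary subunit of Kv4 potassium channels, rose by 3.83 (SE 0.62, adjusted p = 0.0103), the only 1 called of 35 potassium and HCN channel genes and also 1 when adjusted over the list alone. Reln, which encodes the extracellular glycoprotein reelin, made by mitral cells, rose by 3.89 (SE 0.74, adjusted p = 0.0209), from -8.24 ± 1.48 to -4.35 ± 1.55. It was the only 1 called of 18 mitral and tufted cell markers, and also 1 when adjusted over the list alone. Its call ended without P6 control pool 4 (0.0579) and without P6 Kir2.1 pool 2 (0.0528) or 4 (0.0537). Dpysl3, a collapsin response mediator protein of growing axons, fell by 1.24 (SE 0.20, adjusted p = 0.00944), from 3.60 ± 0.14 to 2.36 ± 0.25. Of 29 immature neuron genes, Dpysl3 and Elavl2 (-2.57, adjusted p = 0.0371) were lower and Stmn1 was higher (0.74, adjusted p = 0.0488), against 3 higher and 2 lower adjusted over the list alone. The call of Stmn1 ended without any of the 16 pools and that of Elavl2 without 7 of them, with adjusted p up to 0.0974 and 0.0903. Other settings ended the calls of Kcnip2 (1 of 13, adjusted p up to 0.156), Reln (2 of 13, 0.215) and Dpysl3 (2 of 13, 0.175). They also ended those of Elavl2 (3 of 13, 0.21) and Stmn1 (8 of 13, 0.314).

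Of 42 presynaptic genes, Syp, the vesicle protein synaptophysin (-1.07, SE 0.21, adjusted p = 0.0269), and Rims2, an active zone protein (-2.65, adjusted p = 0.0432), fell, against 2 higher and 5 lower adjusted over the list alone. The call of Syp ended without P6 control pool 4 (0.07) and P6 Kir2.1 pools 2 (0.0621), 3 (0.0517) and 4 (0.0516), and that of Rims2 without 12 pools (up to 0.0961). Scg2 fell by 3.03 (SE 0.64, adjusted p = 0.0337), and its call ended without P6 control pools 1 (0.068), 2 (0.0584) and 4 (0.0702) and P6 Kir2.1 pools 1 (0.0729), 2 (0.0544) and 4 (0.0521). Ret, the receptor of the GDNF family, rose (4.38, adjusted p = 0.0238), as the only 1 called of 50 axon guidance and neurotrophin genes, also adjusted over the list alone. Its call ended without P6 control pool 1 (0.0501) and P6 Kir2.1 pools 1 (0.0648) and 4 (0.0552). Other settings ended the calls of Syp (6 of 13, adjusted p up to 0.21) and Scg2 (6 of 13, 0.149). They also ended those of Rims2 (5 of 13, 0.206) and Ret (3 of 13, 0.215). The activity-regulated genes Arc (-3.04, adjusted p = 0.425), Npas4 (-1.59, 0.683), Egr1 (-1.31, 0.784), Nr4a1 (-0.82, 0.487) and Fos (0.08, 0.988) did not pass, nor did Bmpr2 (0.12, 0.98).

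Markers of olfactory bulb interneurons, the GABAergic cells of the bulb, fell by a mean of 2.46 at P6, with 16 of 17 members negative (adjusted p = 1.36e-05; adjusted p = 0.173 with an estimated correlation). Penk was the 1 called member, and 11 members were lower when adjusted over the list alone. Not past the threshold over all genes were Gad1 (-4.44) and Gad2 (-3.74), the enzymes of GABA synthesis, Slc32a1, the vesicular GABA transporter (-2.42), and the transcription factors Sp8 (-4.47), Dlx5 (-3.00) and Meis2 (-2.13). The interneuron score of each pool differed by -2.46 between the groups (exact two-sided permutation p = 0.0286, the smallest possible, and 0.229 after adjustment over 8 cell type scores). Ribosomal protein genes rose by a mean of 0.26, with 68 of 82 positive (adjusted p = 1.02e-05; adjusted p = 0.664 with an estimated correlation). Genes of oxidative phosphorylation rose by 0.16, with 63 of 91 positive (adjusted p = 0.000711; adjusted p = 0.493 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.098). By limma 0 members of these last 2 lists passed, also adjusted over the list alone, with 9 and 18 at an unadjusted p under 0.05. Many ribosomal proteins have processed pseudogenes whose transcripts a probe may read.

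The remaining 28 lists did not pass at P6, and 27 of them are described. Among cell types, microglia markers changed by a mean of -1.70 (7 of 8 negative, adjusted p = 0.103), with the complement subunit C1qc at -5.01 (at least 7.52-fold, adjusted p = 0.0839) and 2 members lower adjusted over the list alone. Mitral and tufted cell markers had a mean of 0.31 (12 of 18 positive, adjusted p = 0.154), astrocyte and radial glia markers -0.75 (11 of 15 negative, 0.395), and oligodendrocyte lineage markers -0.63 (9 of 13 negative, 0.537). Ensheathing cell markers had -0.78 (8 of 11 negative, 0.537), vascular and blood cell markers 1.05 (6 of 11 positive, 0.395; Esam, an endothelial adhesion molecule, 4.86, at least 6.12-fold) and cell division genes 0.37 (7 of 13 positive, 0.636). Olfactory sensory neuron markers had a mean of -0.33 and a median of -0.22 with a test pointing up (0.636), and 3 of 9 were higher adjusted over the list alone.

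Among neuronal lists, postsynaptic and trans-synaptic adhesion genes had a mean of -0.48 (35 of 46 negative, adjusted p = 0.103), with the adhesion protein Lrrtm1 at -2.78 (adjusted p = 0.0532) and Nlgn3 at -4.44 (0.112). Late activity response genes had -1.10 (15 of 20 negative, 0.154), immediate early genes -0.56 (12 of 18 negative, 0.636) and glutamate receptors -0.78 (15 of 18 negative, 0.291). Potassium and HCN channels had -0.73 (27 of 35 negative, 0.395), GABA and glycine receptors -0.19 (13 of 19 negative, 0.662), presynaptic genes -0.30 (25 of 42 negative, 0.537) and cadherins and protocadherins -0.50 (17 of 26 negative, 0.537). Axon guidance and neurotrophin genes had -0.31 (28 of 50 negative, 0.662), immature neuron genes 0.03 (15 of 29 positive, 0.453) and maturing neuron genes -0.16 (22 of 36 negative, 0.435). Sodium and calcium channels had a mean of -0.07 with a test pointing up (12 of 23 negative, 0.874).

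In signalling and stress, BMP and TGF-beta pathway genes had a mean of -0.02 and a median of -0.39 (21 of 34 negative, adjusted p = 0.537), with the kinase Limk2 at -1.32 (adjusted p = 0.078). Notch and Wnt genes had -0.04 (21 of 36 negative, 0.995), cholesterol synthesis genes 0.06 (13 of 24 positive, 0.636) and unfolded protein response genes -0.08 (15 of 28 negative, 0.95). The mean, median and test also differed in sign for 3 further lists described here. These were heat shock genes (mean -0.08, median -0.09, test up, 0.932), apoptosis and p53 target genes (mean -0.25, median 0.08, test up, 0.862) and X-inactivation and Y-linked genes (3 tested, mean -0.16, median -0.68, test up, 0.95).

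Of the 217 genes at P6, 32 were not well above background on any array of the lower group, 8.1% of named genes did not overlap between the groups (2.86% by chance), and 2068 had an unadjusted p under 0.05 against 602 by chance. A fit of the 8 P6 arrays alone gave 10 genes, while a fit of the P3 arrays alone gave 8 against 1 in the joint fit. The joint fit used 1 spread per gene for all groups. That spread was larger at P6 (root mean square SD over features 1.51 in control, 1.52 in Kir2.1) than at P3 (1.18 and 1.33). The counts at P3 and P6 therefore cannot be compared directly. Among the 31 named genes past the threshold, Iqcb1 (adjusted p up to 0.0429) and Pcdhb16 (0.0477) passed under every setting in which they were tested, left-out pools included. The filter at 8 arrays left Iqcb1 out. Without P6 control pool 4 the count was 124, and without P6 Kir2.1 pool 1, 2 or 4 it was 113, 137 or 106. With P6 control pools 2 and 4 only it was 173, of which 124 were higher and 49 lower. The split also moved with scaling over all probes (159 higher and 63 lower) and with the deposited value table (153 and 63), and it turned with the normexp background correction (141 higher and 292 lower), so the balance of higher and lower genes depends on the processing. Scaling over all probes shifted the median change of all genes from -0.09 to 0.12 and the normexp background correction to -0.20.

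Averaged over P3 and P6, the comparison asked for the mean difference of the ages, which 1 age alone can carry, and it gave 85 named genes, 40 higher and 45 lower with Kir2.1. Lhfp, which encodes a tetraspan membrane protein, rose by 2.13 (SE 0.20, adjusted p = 0.000942), from -0.67 ± 0.15 to -0.06 ± 0.16 at P3 and from -4.67 ± 0.60 to -1.0 ± 0.28 at P6. Reln rose by 3.40 (SE 0.52, adjusted p = 0.0118) and Vldlr, a reelin receptor, by 1.86 (SE 0.32, adjusted p = 0.0181). Kcnip2 rose by 2.80 (SE 0.44, adjusted p = 0.0123), from -4.63 ± 0.44 to -2.85 ± 0.22 at P3 and from -7.75 ± 1.63 to -3.92 ± 0.63 at P6. Pdcd6ip, the ESCRT-associated protein ALIX, rose by 2.41 (SE 0.40, adjusted p = 0.0155).

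Arhgap22 fell by 4.78 (SE 0.59, adjusted p = 0.00402), at least 5.4-fold at P3 and 14.2-fold at P6, Scg2 by 4.32 (SE 0.46, adjusted p = 0.00154) and Pik3cb by 4.27 (SE 0.46, adjusted p = 0.0016). Pik3cb lay at -5.43 ± 0.71 and -9.45 ± 0.29 in control and Kir2.1 cells at P3, at least 3.78-fold, and at -4.46 ± 0.79 and -8.97 ± 1.57 at P6. These 8 genes separated the groups at each age and passed under every setting run and without each pool. Derl1 fell (-1.72, adjusted p = 0.0118) and Rab39b, a small GTPase, rose (2.98, adjusted p = 0.0116; at least 1.69-fold at P6). Both also passed without each pool, but 1 other setting ended each call (adjusted p = 0.316 and 0.195). Senp7 (2.71) and Zfp672 (-2.42) passed too, but another probe of each moved the other way, and other settings ended both calls (adjusted p up to 0.601 and 0.627). With limma 26 of the genes named passed, of which 12 did so without each pool.

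Of the 31 lists, 3 passed for the averaged difference. Ribosomal protein genes rose by a mean of 0.21, with 77 of 82 positive (adjusted p = 2.76e-10; adjusted p = 0.555 with an estimated correlation), while by limma 0 members passed, also adjusted over the list alone, with 11 at an unadjusted p under 0.05. Interneuron markers had a mean of 0.34 at P3 (adjusted p = 0.622) and of -2.46 at P6, and on average fell by 1.06, with 14 of 17 negative (adjusted p = 0.0127; adjusted p = 0.48 with an estimated correlation), and with 0 members called by limma against 2 lower adjusted over the list alone and 2 at an unadjusted p under 0.05. Their call ended without P6 control pool 1 (0.11) or P6 Kir2.1 pool 4 (0.0641), with P6 control pools 2 and 4 only (0.236) and with the filter at 8 arrays (0.11). Late activity response genes fell by 0.83, with 13 of 20 negative (adjusted p = 0.0306; adjusted p = 0.48 with an estimated correlation). Scg2 and Acan, the proteoglycan aggrecan (-2.03, adjusted p = 0.0338), were called among them, the latter not without 11 of the 16 pools (up to 0.0709) or under 4 of 12 other settings (up to 0.0751), and 4 were lower adjusted over the list alone. That list lost its call without P3 control pool 3 (0.0539), P3 Kir2.1 pool 2 (0.0572), P6 control pools 1 (0.115), 2 (0.0705) or 4 (0.0549), or P6 Kir2.1 pool 2 (0.123), and under 5 of 12 other settings (up to 0.48).

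The averaged count of 85 fell to 46, 37, 48 and 35 without P3 control pools 1 to 4, to 38, 38 and 43 without P3 Kir2.1 pools 1, 2 and 4, and to 41 and 56 without P6 control pool 4 and P6 Kir2.1 pool 4, and it was 138 without P6 control pool 3. The share of higher genes was 47.1%, against 63.5% with scaling over all probes (73 higher and 42 lower) and 63.4% with the deposited value table, but 38.1% with the normexp background correction (61 higher and 99 lower). Across genes, which are not independent replicates, the differences at P3 and P6 correlated with r = 0.07, and 133 of the 217 genes called at P6 (61.3%) had the same direction at P3.

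The comparison of P6 with P3 in control cells described normal maturation, and since each age lay on its own slide, age and slide cannot be told apart. It gave 318 named genes, 159 higher and 159 lower at P6. Otop2, a proton channel, rose by 8.42 (SE 1.18, adjusted p = 0.00313), at least 93.7-fold, and Vgf, a neurosecretory peptide precursor, by 6.69 (SE 1.20, adjusted p = 0.011). Rasal1, a Ras GTPase-activating protein, rose by 6.27 (adjusted p = 0.00738), at least 21-fold. Zfp777, a zinc finger protein, fell by 6.70 (SE 0.76, adjusted p = 0.00158), at least 22.6-fold, B3gnt9 by 6.16 (adjusted p = 0.00147), at least 23.1-fold, and Snhg12 by 6.52 (adjusted p = 0.00596).

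Synaptic genes rose with age in control cells. Of 42 presynaptic genes 29 were positive, with a mean of 0.62 (adjusted p = 1.96e-05; adjusted p = 0.0422 with an estimated correlation), 5 were called higher, and 11 were higher and 1 lower adjusted over the list alone. Among them were Syn2, a synapsin of vesicle clusters (3.91, adjusted p = 0.00313), Rims2 (3.16, 0.0153), Syp (1.80, 0.00196) and Snap25, a SNARE protein (1.24, 0.00431). Postsynaptic and adhesion genes rose by a mean of 0.60, with 37 of 46 positive (adjusted p = 0.000313; adjusted p = 0.0339 with an estimated correlation), with 1 called and 3 higher adjusted over the list alone. Sodium and calcium channels rose by 1.01 (18 of 23 positive, adjusted p = 0.00501; adjusted p = 0.0357 with an estimated correlation), with 2 higher and 1 lower, against 4 and 1 adjusted over the list alone. Potassium and HCN channels rose by 0.81 (25 of 35 positive, adjusted p = 0.0233; adjusted p = 0.0422 with an estimated correlation), with 2 higher, 1 of them the channel Kcnma1 (2.28, adjusted p = 0.00384), and 1 lower, against 5 and 1 adjusted over the list alone. Glutamate receptors rose by 0.73 (13 of 18 positive, adjusted p = 0.0243; adjusted p = 0.0836 with an estimated correlation), with 1 called, also adjusted over the list alone. Their call ended without P6 control pool 1 (0.0562) or 3 (0.0606).

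Genes of immature neurons fell with age in control cells by a mean of 0.51, with 22 of 29 negative (adjusted p = 0.000313; adjusted p = 0.0379 with an estimated correlation). Of these 5 were called lower and 1 higher, against 10 and 1 adjusted over the list alone. The cytoskeletal genes Tuba1a (-1.34, adjusted p = 0.00354), Stmn1 (-1.28, 0.00311) and Tubb2b (-1.24, 0.00313) fell, while Dclk1, a microtubule-associated kinase, rose (2.89, 0.00731). Genes of maturing neurons rose by 0.65 (24 of 36 positive, adjusted p = 0.000543; adjusted p = 0.071 with an estimated correlation), with 5 called higher, against 9 higher and 1 lower adjusted over the list alone. Late activity response genes rose by 1.36 (18 of 20 positive, adjusted p = 0.000576; adjusted p = 0.0357 with an estimated correlation), with 2 called, Vgf and Rasgrp1, also adjusted over the list alone. The call of Rasgrp1 (adjusted p = 0.0357) ended without 7 of the 16 pools (up to 0.0951) and under 3 of 13 other settings (up to 0.0946). Immediate early genes rose by 1.91 (14 of 18 positive, adjusted p = 0.00259; adjusted p = 0.177 with an estimated correlation), but by limma 0 members passed, also adjusted over the list alone, with 6 at an unadjusted p under 0.05. Among them were Npas4 (5.47, adjusted p = 0.118) and Arc (5.06, adjusted p = 0.173).

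Markers of interneurons, astrocytes and radial glia, and microglia also rose between P3 and P6 control pools, which moved with the synaptic and activity-related lists. The mitral and tufted cell, oligodendrocyte lineage, ensheathing cell, vascular and blood cell, and olfactory sensory neuron lists did not pass. Mitral and tufted cell scores lay at -2.33, -2.42, -2.63 and -1.93 in P3 control pools 1 to 4 and at -1.33, -1.62, -2.15 and -1.63 in P6 control pools 1 to 4. Interneuron markers rose by a mean of 2.86, with 15 of 17 positive (adjusted p = 6.85e-08; adjusted p = 0.0263 with an estimated correlation), and with 5 called, against 8 higher adjusted over the list alone. The transcription factor Meis2 rose by 4.32 (adjusted p = 0.00313) and Gad2 by 6.87 (adjusted p = 0.0158), from -7.83 ± 2.41 to -0.96 ± 1.32, a call that ended without P3 control pool 3 (0.0574). Astrocyte and radial glia markers rose by 1.97 (14 of 15 positive, adjusted p = 2.81e-05; adjusted p = 0.0263 with an estimated correlation), with 1 called, against 3 adjusted over the list alone. Microglia markers rose by 2.06 (7 of 8 positive, adjusted p = 0.000618; adjusted p = 0.0339 with an estimated correlation). Of these the integrin Itgam was called (1.19, adjusted p = 0.0046), against 3 adjusted over the list alone. With P6 control pools 2 and 4 only, the microglia (adjusted p = 0.0706), glutamate receptor (0.201) and potassium channel (0.115) calls ended, the last also with the mean of a gene's probes (0.0887).

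Genes of oxidative phosphorylation fell with age in control cells by a mean of 0.42 (76 of 91 negative, adjusted p = 2.61e-07; adjusted p = 0.0836 with an estimated correlation), with 2 called and 14 lower adjusted over the list alone. Ribosomal protein genes fell by 0.45 (76 of 82 negative, adjusted p = 9.83e-10; adjusted p = 0.231 with an estimated correlation), with 1 called and 6 lower adjusted over the list alone. In all, 14 of the 31 lists passed. Groups did not overlap in 12.6% of named genes (2.86% by chance), and 36 called genes were not well above background on any array of the lower group. The count of 318 fell to 145, 181, 133 and 176 without P3 control pools 1 to 4 and to 185 without P6 control pool 4, was 210 with P6 control pools 2 and 4 only, and 105 when only control arrays were fitted. Of the 19 genes called with age in control cells and named above, 10 besides Rasgrp1 lost their call under 1 or 2 of 13 other settings. These were Kcnma1, Dclk1 and Itgam (adjusted p up to 0.563, 0.346 and 0.238), Vgf (0.0661), Snhg12 (0.0649), Rims2 (0.0644), Gad2 (0.0614), Snap25 (0.0601), Tuba1a (0.0584) and Tubb2b (0.0546).

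**Figure D2:**
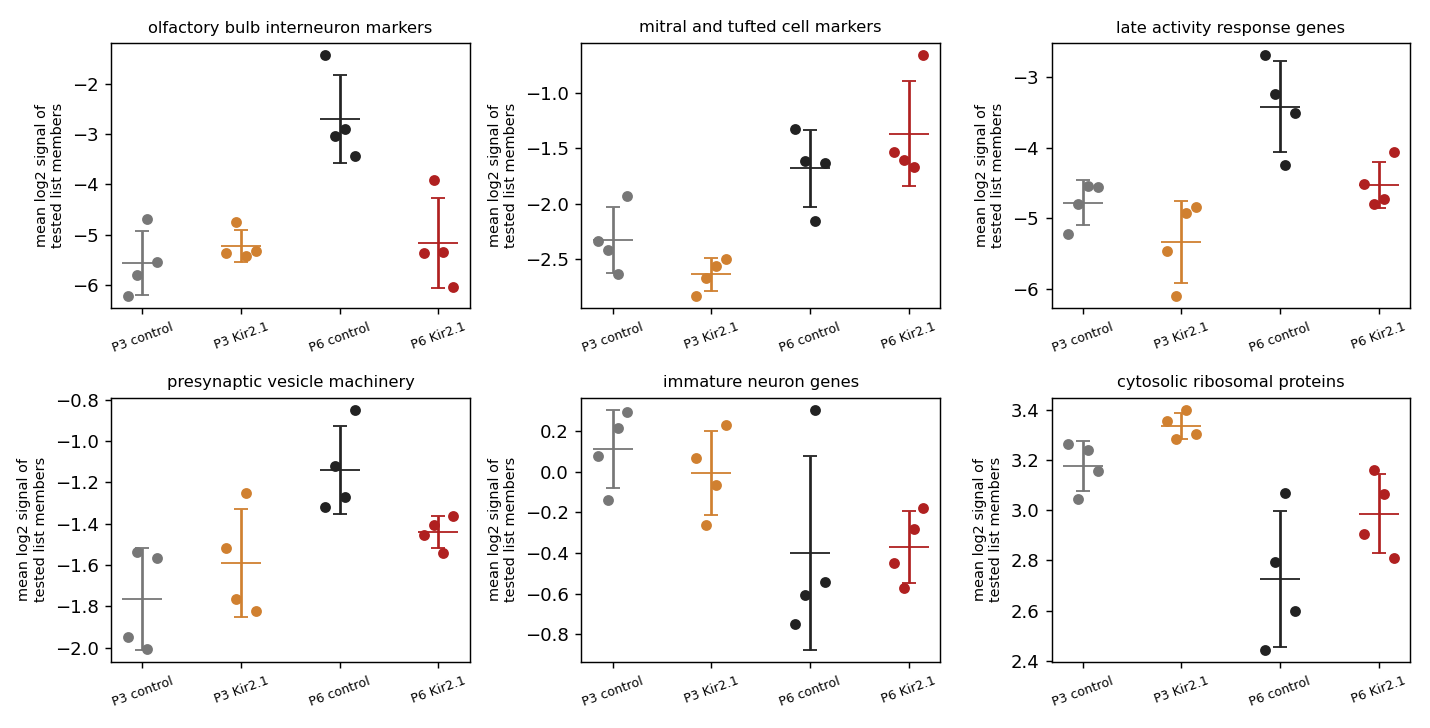
Mean log2 signal, relative to the 75th percentile of each array, of the tested members of 6 gene lists (y axis) in the 4 groups (x axis). Points are pools, lines are means and bars are the SD over 4 pools; interneuron markers rise by a mean of 2.86 from P3 to P6 control pools and lie lower by -2.46 in P6 Kir2.1 than in P6 control pools.

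In Kir2.1 cells, P6 against P3 gave 115 named genes, 69 higher and 46 lower, with the same limit that each age lay on its own slide. Lbhd2, a marker of mitral cells, rose by 8.54 (SE 0.96, adjusted p = 0.00262), from -7.90 to 0.64. It also passed with age in control cells by limma (adjusted p = 0.0381). That call ended without 7 of the 16 pools (up to 0.1) and under 2 of 13 other settings (up to 0.081). Rasgrp1, a Ras activator, rose by 6.24 (SE 0.89, adjusted p = 0.0118), B2m, the light chain of MHC class I, by 6.01 (adjusted p = 0.0102), and Inpp5j, an inositol phosphatase, by 6.46 (adjusted p = 0.0148). Scg2 rose by 4.29 (adjusted p = 0.0148), from -8.0 ± 1.22 to -3.71 ± 1.22, and Zfp773 fell by 4.52 (adjusted p = 0.00516), at least 7.66-fold. The synaptic adhesion protein Nlgn1 (4.82, at least 10.4-fold, adjusted p = 0.0149) and the amino acid transporter Slc38a3 (5.33, 0.0155) rose and the microtubule protein Mapt fell (-1.26, 0.016), but these calls ended without P3 Kir2.1 pool 4 (each 0.0511).

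Of the 31 lists, 7 passed with age in Kir2.1 cells. Mitral and tufted cell markers rose by a mean of 1.27, with 13 of 18 positive (adjusted p = 0.000107; adjusted p = 0.087 with an estimated correlation), and with 4 called, against 7 higher and 2 lower adjusted over the list alone. Genes of maturing neurons rose by 0.90 (26 of 36 positive, adjusted p = 1.26e-05; adjusted p = 0.0568 with an estimated correlation), with 4 higher and 1 lower, against 12 and 4 adjusted over the list alone, among them Olfm1, a secreted glycoprotein (1.68, adjusted p = 0.00886). Sodium and calcium channels rose by 1.04 (17 of 23 positive, adjusted p = 0.000301; adjusted p = 0.0309 with an estimated correlation), with 1 called and 3 adjusted over the list alone. Presynaptic genes rose by 0.15 (28 of 42 positive, adjusted p = 0.000823; adjusted p = 0.171 with an estimated correlation), with Erc2, an active zone protein, called (2.12, adjusted p = 0.00796), against 6 higher and 1 lower adjusted over the list alone. Late activity response genes rose by 0.81 (12 of 20 positive, adjusted p = 0.000642; adjusted p = 0.0568 with an estimated correlation), with 3 called and 5 adjusted over the list alone. Ribosomal protein genes fell by 0.35 (76 of 82 negative, adjusted p = 9.54e-08; adjusted p = 0.314 with an estimated correlation), where by limma 0 passed over all genes, 1 was lower adjusted over the list alone and 25 had an unadjusted p under 0.05.

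Astrocyte and radial glia markers rose by 0.82 in Kir2.1 cells (11 of 15 positive, adjusted p = 0.0427; adjusted p = 0.172 with an estimated correlation), where by limma 0 members passed, 1 was higher adjusted over the list alone and 2 had an unadjusted p under 0.05. Their call ended without P3 Kir2.1 pool 3 (0.172), P6 Kir2.1 pool 3 (0.128) or P6 control pool 1 (0.0521), and under scaling over all probes (0.0954), quantile normalization (0.0851), the deposited value table (0.0917) and the filter at 8 arrays (0.105). Interneuron markers had a mean change of 0.06 (adjusted p = 0.498). In both treatments 29 genes changed with age, 28 of them in the same direction, where independent lists would share 3.04, and the changes correlated across genes with r = 0.235. Both comparisons set slide 2 against slide 1, which the value for independent lists leaves out. A difference between the slides may therefore give such an overlap. The count of 115 fell to 43, 64 and 21 without P3 Kir2.1 pools 2 to 4, to 49, 59 and 55 without P6 Kir2.1 pools 1, 2 and 4, and to 17 when only Kir2.1 arrays were fitted. Of the 11 genes called with age in Kir2.1 cells and named above, all but Lbhd2 and Zfp773 lost their call under 1 to 4 other settings, with adjusted p up to 0.116 for Rasgrp1, 0.0628 for B2m, 0.073 for Inpp5j, 0.123 for Scg2 and Erc2, 0.156 for Olfm1, 0.15 for Nlgn1, 0.104 for Slc38a3 and 0.13 for Mapt. The share of higher genes was 60%, against 72.1%, 72.4% and 72% with scaling over all probes, quantile normalization and the deposited value table, and 56.8% with the normexp background correction.

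The interaction asked whether the difference between Kir2.1 and control cells itself differed between P3 and P6, and 7 named genes were higher and 2 lower. Lhfp (3.06, SE 0.39, adjusted p = 0.00975), Chaf1b, a subunit of a histone chaperone (6.07, SE 0.81, adjusted p = 0.0111), and Alkal1, a ligand of the receptor ALK (5.02, SE 0.59, adjusted p = 0.00975), passed without each pool. Chaf1b lay at -1.55 and -2.90 in control and Kir2.1 cells at P3 and at -6.11 ± 0.38 and -1.39 ± 0.79 at P6. Alkal1 lay at -8.22, -9.30, -9.35 and -5.40 ± 0.62 in the same order and was not well above background on any array of the first 3 groups, so its size is a difference from background (at least 4.53-fold between Kir2.1 and control at P6). With the normexp background correction its interaction was 0.60 (adjusted p = 0.591). Iqcb1 (8.60, adjusted p = 0.0272; not well above background in P3 Kir2.1 and P6 control), the RNA-binding protein Raly (4.56, 0.0272) and Zfp664 (2.21, 0.0362) were higher and Usp17la (-2.71, 0.0272) and Smo, the transducer of hedgehog signals (-1.64, 0.0362), lower. Those 5 calls ended without 11, 8, 13, 10 and 14 of the 16 pools, with adjusted p up to 0.0804, 0.0756, 0.104, 0.0798 and 0.105, and under 2, 1, 3, 3 and 6 other settings (up to 0.1, 0.124, 0.864, 0.089 and 0.487). The other probe of Zfp664 moved the other way, and Usp17la belongs to a family of near-identical genes. The remaining gene, also higher, carries only a clone identifier and is given as a count.

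For 3 lists the difference between treatments changed with age. Interneuron markers had an interaction of -2.80, with 15 of 17 negative (adjusted p = 6.26e-05; adjusted p = 0.153 with an estimated correlation), and microglia markers of -2.18, with 7 of 8 negative (adjusted p = 0.0118; adjusted p = 0.153 with an estimated correlation). The microglia call ended without P6 control pool 1 (0.0507) and with P6 control pools 2 and 4 only (0.398). Genes of oxidative phosphorylation had an interaction of 0.24, with 63 of 91 positive (adjusted p = 0.000745; adjusted p = 0.476 with an estimated correlation). By limma 0 members of these 3 lists passed over all genes, 4, 1 and 0 were lower adjusted over the list alone, and 7, 3 and 12 had an unadjusted p under 0.05. At an unadjusted p under 0.05 lay 1265 named genes, against 602 by chance. The count of 9 was 4, 4 and 5 without P3 control pools 1 to 3, 4 and 5 without P3 Kir2.1 pools 2 and 4, and 14, 23 and 5 without P6 control pools 1, 2 and 4. It was 18 with P6 control pools 2 and 4 only and 34 (9 higher and 25 lower) with the normexp background correction.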

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

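The counts of interneuron and oligodendrocyte markers and the comparison of interneuron markers with those of other cell types were chosen, with their bounds, after their results were seen; the other tests were written down before. A pool is listed as standing apart where its gap to the nearest of the other 3 pools of its group took up most of the group's range. Chance gives this in about 1 in 20 groups, and it was found in 46 of 504 groups, or 9.1%, over 4 array measures, 5 list means and 37 gene values.

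For 8 of the 9 genes that passed, those with a gene name beyond a clone identifier, the difference between Kir2.1 and control cells differed between P3 and P6 by the test of the interaction. On the log2 scale it was 8.60 for Iqcb1, 6.07 for Chaf1b, 5.02 for Alkal1, 4.56 for Raly, 3.06 for Lhfp and 2.21 for Zfp664, and it was -2.71 for Usp17la and -1.64 for Smo. Alkal1 was well above background in P6 Kir2.1 pools only, and Iqcb1 in no P3 Kir2.1 or P6 control pool. The list test of the interaction, with a preset correlation, gave a mean of -2.80 for interneuron markers, -2.18 for microglia markers and 0.24 for oxidative phosphorylation genes, calls that ended with an estimated correlation (adjusted p = 0.153, 0.153 and 0.476).

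Interneuron markers, none of which is on another list, were lower in P6 Kir2.1 than in P6 control pools for 16 of 17 tested genes. The list call held under 3 other scalings (highest adjusted p of the list test 3.75e-06 with the preset correlation), but this decides little. The test sets the list against the other genes, and scaling over all probes is nearly the same as the deposited value table. Under the main and the other scalings the median change of all genes ran from -0.09 to 0.12. That is small beside the list's mean of -2.46 and argues against the scaling of the arrays as its cause. The call itself ended with an estimated correlation (adjusted p = 0.173). A lower share of mitral cells in the control pools stays open, because the gap between the interneuron score and the mean score of 5 other cell types differed by -1.90 between Kir2.1 and control pools (exact two-sided permutation p = 0.0286, the smallest possible), but by -1.49 with overlapping groups (exact two-sided permutation p = 0.0857) without the vascular and blood cell list, which was high in Kir2.1 pools 1 and 2 (-3.28 and -2.40). RNA of interneurons picked up with mitral cells of the P6 control pools is a candidate explanation, with Gad2 at -0.96 and Meis2 at -0.36 in those pools, although picking by EYFP and the PCR selection for Pcdh21 would have removed a lone interneuron. How many of these genes mitral cells express is not known here, so their expression by the mitral cells themselves, and a lower expression with Kir2.1, stay open and were not tested, as does the row of the slide.

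Several oligodendrocyte lineage markers were high in P6 control pool 3, with Olig1 at 1.66 against at most -0.41 in the other 15 arrays, Olig2 at -0.37 against -4.91, Pdgfra at -1.53 against -5.14, Cnp at 0.76 against -1.47 and Bcas1 at -0.18 against -2.94. A brighter array is argued against, since before scaling the 75th percentile of its processed signal was 54.0. That percentile was 105.0, 38.2 and 51.5 in P6 control pools 1, 2 and 4. Of all tested named genes 8.5% had their highest value in pool 3. Scaling had already removed most differences in brightness, so that share decides little. RNA of an oligodendrocyte lineage cell in that pool could not be decided, because 5 of 13 markers had their highest value there, between the 6 taken as needed for it and the 3 taken as arguing against it, both chosen after the values were seen, and picking by EYFP and the PCR selection for EYFP and Pcdh21 would have removed a lone cell of that kind. The myelin gene Mbp (-1.02 against up to -0.43 in another array) was not highest there. Sox10 narrowly missed the highest value (-0.62 against up to -0.49 in another array and a median of -5.65 over the others). It is also on the ensheathing cell list. No explanation from the mitral cells themselves was tested for this pool.

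Splits of the same arrays into groups of the same sizes were counted with the real one included. No other split reached the number of genes called at P6 (1 of 35 splits, the real one, reached 217, against at most 9 in another split), a share under the bound set beforehand. The same held with age in control cells (1 of 35, 318 against 4), with age in Kir2.1 cells (1 of 35, 115 against 6) and averaged over both ages (1 of 100, 85 against 12). Chance cannot be excluded for the 1 gene at P3, where 10 of 35 splits, the real one included, gave as many and the highest other gave 2. For the interaction 2 of 100 splits reached 9 genes, under the bound set beforehand, but the other one gave 10. These splits mixed Kir2.1 and control pools within each age. That also removed any Kir2.1 difference shared by both ages, so they cannot decide on the interaction alone. The shares of splits were not adjusted for the number of counts tested. Since 1 of 35 is the smallest share that 35 splits can give, such a share alone does not exclude chance. For the number of lists past the threshold at P3, no other split reached the real count (1 of 35, 4 against 2), a share under the bound set beforehand. However, all 4 calls ended with an estimated correlation (adjusted p = 0.356 to 0.736) and 3 of them under 7 to 10 of 13 other settings. Chance cannot be excluded for the lists at P6 (6 of 35, 3 against 5), with age in control cells (2 of 35, 14 against 14), with age in Kir2.1 cells (4 of 35, 7 against 8), averaged (12 of 100, 3 against 5) or for the interaction (19 of 100, 3 against 7).

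Among array measures, P3 control pool 4 had 35.3% of probes well above background against 36.3% to 36.4% in the other 3 pools, and P6 control pool 1 had 41.1% against 34.7% to 35.5%. The median of the deposited values was 0.049 in P3 control pool 4 and 0.12 in P3 Kir2.1 pool 3. Among list means, mitral and tufted cell markers lay at -0.67 in P6 Kir2.1 pool 4, interneuron markers at -4.76 in P3 Kir2.1 pool 2, vascular and blood cell markers at -6.74 in P6 control pool 4, Notch and Wnt genes at -6.14 in P6 Kir2.1 pool 1, and unfolded protein response genes at -2.24 in P6 Kir2.1 pool 3.

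Single genes stood apart in each group. In P3 control pool 4, Otop2 (-8.97), Pipox (-8.93) and Rasal1 (-8.29) were not well above background on any array of the group, so their place reflects background and not expression. The others there were Cpa6 (-5.53), Kitl (-5.67), Osbpl9 (-6.75) and Pcp4l1 (-4.31), and in pool 3 they were Arc (-4.68), Bmpr2 (-5.88), Rbfox3 (-6.82), Rdm1 (-5.30), Zfp773 (-4.94) and Zfr (-5.93), each the highest of its group. In pool 2 Hspb3 (-6.38), Nudt1 (-3.36) and Pcdh7 (-6.33) were the highest, and in pool 1 Ctxn2 (-3.92) was the lowest. In P3 Kir2.1 pool 2 Cpa6 (-5.40), Khk (-5.12), Otop2 (-2.61) and, on no array of the group well above background, Penk (-7.13) were the highest and Reln (-2.65) the lowest, and in pool 1 Amn (-1.85) and Vldlr (0.41) were the highest. In P3 Kir2.1 pool 4 Fos (-3.08) and Nr4a1 (-4.30) were the highest and Tnks (-4.22) and Zfp777 (-5.43) the lowest, and in pool 3 B3gnt9 (-4.74) was the lowest. In P6 control pool 3 Bmpr2 (-3.14) and Lhfp (-3.77) were the highest and Col2a1 (-4.80) the lowest. In P6 Kir2.1 pools, Scg2 (-5.52) and Vgf (-9.81) were the lowest in pool 1, while Aldh5a1 (-2.98) in pool 2, Sstr1 (-2.09) in pool 3 and Itgb3 (-5.62) in pool 4 were the highest.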

How the results depend on the processing

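Scaling over all probes, the normexp background correction and the fit with P6 control pools 2 and 4 only were chosen after the results were seen, the other settings before. The causes of these moves were not tested. Fits of fewer arrays hold fewer samples, but that alone does not account for the moves. The P3 arrays alone gave more genes than the joint fit (8 against 1), and the P6 arrays alone gave fewer (10 against 217). Such fits also use the spread of their own groups only, which was larger at P6 than at P3. Named genes past the threshold kept their direction in every setting but the mean of a gene's probes, which gave Camk2b -0.17 with age in control cells and Zfp664 -0.67 for the interaction, since their probes disagree. With every probe tested separately, only the probe that stood for the gene was compared. Other probes of Asph, Senp7, Zfp672 and Zfp664 moved the other way. Over all other settings, 2269 gene results kept their side of the threshold, 469 fell short of it and 20 newly passed, and over left-out pools these were 2672, 824 and 8. These gene results include named genes that did not pass in the main fit and count as kept where they stayed short. The share kept therefore overstates how often calls held. List results kept their side in 373 cases and fell short in 63, and over left-out pools these were 505 and 39.

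With the normexp background correction the counts were 433 genes at P6 (141 higher and 292 lower, 168 of the 217 kept in direction), 160 averaged and 34 for the interaction. Without a filter on dim probes they were 114 at P6, 40 averaged and 170 with age in control cells, with 67 list calls against 34, and 106 of the 165 calls of named genes were kept. The filter at 8 arrays gave 3 at P3 and 15 for the interaction, and every probe tested separately gave 2 at P3. Array weights gave 7 at P3 and 100 at P6, all 100 of them among the 217. The trended and robust prior gave 374 at P6, 176 averaged, 510 with age in control cells and 58 for the interaction. P6 control pools 2 and 4 only gave 2 at P3, 210 with age in control cells, 18 for the interaction and 83 calls of named genes. Only the groups of a comparison gave 8 at P3, 10 at P6, 105 with age in control and 17 with age in Kir2.1 cells. An estimated correlation left 10 of the 34 list calls.

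The replicate numbers do not pair the pools, since deviations of pools with the same number correlated between -0.028 and 0.031 over 24 pairs. With the replicate number as a block (replicate block) the counts were 0 at P3 by limma (733 genes at an unadjusted p under 0.05, and Scg2 at an adjusted p of 0.108), 112 at P6, 39 averaged, 198 with age in control and 35 with age in Kir2.1 cells, 5 for the interaction and 91 calls of named genes. Of the calls without the block it kept 106 at P6 and 37 averaged.

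Leaving out 1 pool at a time, the counts ranged from 0 to 3 at P3, from 106 to 228 at P6, from 35 to 138 averaged, from 133 to 352 with age in control cells, from 21 to 125 with age in Kir2.1 cells, from 4 to 23 for the interaction, from 29 to 36 for list calls and from 97 to 135 for calls of named genes. The highest counts averaged and at P6 came without P6 control pool 3, and the named calls were 105, 104, 103 and 106 without P3 control pools 1 to 4, 103 without P3 Kir2.1 pool 4, 97 without P6 control pool 4 and 105 without P6 Kir2.1 pool 4, against 165. At P3 limma gave 0 without P3 control pool 1 or 2 or P3 Kir2.1 pool 3 or 4 (637, 593, 783 and 669 genes at an unadjusted p under 0.05), 3 without P3 Kir2.1 pool 1, and 2 without P6 control pool 4 or P6 Kir2.1 pool 4. Signal over background limits the genes that could be tested, since 20494 probes were well above background on 0 arrays. The planned normexp version on mean signals was not run.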

Other observations

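The counts of genes shared with simulated and with separate control pools, and the genes named in this paragraph, were chosen after the results were seen, and the other tests before. Genes that differed with Kir2.1 at P6 often differed the other way with age in control cells. In all, 76 named genes passed both tests, 47 of them higher with Kir2.1 and lower with age and 29 the reverse. Lhfp was higher with Kir2.1 at P6 (3.66) and lower with age (-4.00), and so were Chaf1b (4.72 and -4.56), Pdcd6ip (4.19 and -3.56), Vldlr (2.57 and -1.88) and Emx1, a forebrain transcription factor (2.41 and -2.31). Bcl11a, a transcription factor of developing neurons, had 1.26 and -1.56. Kitl was lower with Kir2.1 (-6.19, at least 25.1-fold) and higher with age (5.32), as were Plppr5, a neuronal membrane protein (-4.66 and 4.17), the chloride-proton exchanger Clcn3 (-2.23 and 1.75), the sodium-calcium exchanger Slc8a3 (-0.89 and 1.36) and Dnajc5, a chaperone of synaptic vesicles (-0.85 and 0.80). Adjusted p values by limma reached 0.046 with Kir2.1 (Slc8a3) and 0.045 with age (Dnajc5), and the calls of Emx1, Bcl11a, Plppr5, Clcn3, Slc8a3 and Dnajc5 were not recomputed with single pools left out.

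Both comparisons use the P6 control pools, so part of this opposition comes from the shared pools. The changes correlated across genes, which are not independent replicates, with r = -0.609, where simulated unchanged groups against the same pools gave -0.501. The covariance was -1.211, against -0.565 in the simulation, a difference of -0.646. The simulation gave every group the same spread per gene, the mean over the 4 groups. The shared P6 control pools spread more than the P3 pools (root mean square SD over features 1.51, against 1.18 in P3 control and 1.33 in P3 Kir2.1). It therefore understates the part from shared pools, and the difference does not measure what remains. In 100 simulations of unchanged groups limma called at most 1 gene in a comparison and none in both, a value that leaves out real effects and the unequal spread of the groups. Independent lists would share 1.51 and 1.36 genes in the 2 opposite directions, a value that leaves out the shared pools, so the excess of the 76 genes over either is not a measure of a shared effect. With separate P6 control pools on each side, in fits with fewer control arrays per comparison, 10 to 17 genes were called in both in opposite directions, where independent lists would share 0.64 to 1.17, and up to 2 in the same direction. With these separate pools the correlation was -0.203 on average over 6 divisions (-0.217 to -0.179), which argues against the shared pools as the whole cause.

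The hypothesis was that P6 Kir2.1 pools lie nearer to P3 control pools than P6 control pools do. Across all tested named genes their mean correlation with P3 control pools was 0.781 (SD 0.017), against 0.758 (SD 0.012) for P6 control pools, a difference of 0.023 that did not pass (exact two-sided permutation p = 0.0571). Over the 6460 genes well above background on all arrays the difference was 0.019 (exact two-sided permutation p = 0.171), so noise of dim probes stays open. Slower maturation with Kir2.1 is a candidate explanation that these values do not settle, and RNA of other cells in the P6 control pools may give the same pattern. The gene lists did not point 1 way. Maturing neuron genes rose with age by 0.65 in control and 0.90 in Kir2.1 cells, but presynaptic genes by 0.62 and 0.15. With Kir2.1 at P6, immature (0.03) and maturing neuron genes (-0.16) did not pass the list test (adjusted p = 0.453 and 0.435).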
